A study of Bos taurus with 16 samples.

How the data were processed

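Expression was measured in mammary gland tissue of Holstein Friesian cows on 16 Agilent 2-colour bovine oligonucleotide arrays. Per the labels, total RNA was extracted with a column kit, pooled, amplified and labelled with Cy3 or Cy5, and each array carried RNA of infected tissue in 1 dye and RNA of healthy tissue in the other. Each of the 4 infected groups had 2 biological replicates, and each replicate was hybridised on 2 arrays with the dyes exchanged. The infected sample was in Cy3 on the first array of a pair and in Cy5 on the second, per the labels. The labels call replicates biological and RNA pooled, without saying which cows entered which pool. The p-values measure only the spread between both pools of a group, on 1 slide, which may be technical. They omit spread between slides and of the healthy reference. The few arrays and pools limit the precision of every value.

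The deposited scanner files hold foreground and local background intensity of each spot in both channels, made with Agilent Feature Extraction 10.10.1.1 and its protocol GE2_1010_Sep10, per the file headers. The same deposited files hold a log10 ratio of Cy5 to Cy3 that the scanner software corrected for background and dye, and it was used only as an alternative. A log2 ratio per spot is held in the authors' series values. Set against the scanner ratios, it was already turned to infected over healthy on all 16 arrays and centred near 0 on each. The medians of its columns, from array 1 to array 16, were 0.0077, 0.0020, 0.011, 0.0012, -0.016, 0.0094, 0.014, -0.021, 0.011, -0.0017, 0.0084, 0.0066, 0.015, 0.0080, 0.018 and -0.013. How the authors normalised it is not given in the sources used here, so it too served only as an alternative. Each slide held 4 arrays of 1 group, and scan 1 held only the CoPS group of lactations 1 and 2.

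Spot intensities were read into R 4.3.3 and analysed with limma 3.58.1, with version 1.17.8 of data.table and 1.5.0 of statmod. Background was corrected by normexp with an offset of 50 on mean foreground and median local background, and each array was normalised by loess with control spots at weight 0. Control spots and 1068 spots with outlier flags were then left out, and saturated spots were kept. Spots of a probe were averaged, ratios were turned to infected over healthy, and the arrays of each dye swap were averaged, which gave 8 replicate values per probe. A probe was kept if it was well above background in at least 1 channel on at least 4 of the 16 arrays, which left 34152 probes. Each gene was represented by its brightest probe, and 20363 genes with values in at least 6 replicates were tested. The lowest correlation between arrays of the same dye orientation was 0.232, so no array ran against the others.

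Of 43653 probes outside the controls, 23509 were named through their accession and 1632 through another accession of the same probe in a RefSeq gene table of assembly ARS-UCD2.0, which was used for names alone. The other 18512 kept the name in the file, and 3334 symbols differ from the file's older gene name. Probe coordinates are those of the files, whose build field reads Btau_3.1; no sequence or annotation of that build was used here. Of the tested genes, 13067 have a symbol. Among genes with several probes, another probe was called in the opposite direction for 584 of 6150 called genes in CoPS against healthy, 431 of 5051 in CoNS against healthy and 59 of 3097 in CoPS against CoNS. Beta-defensins, cathelicidins, serum amyloid A genes, SERPINA3 genes and the BOLA genes of the major histocompatibility complex belong to families of near-identical copies, so which copy a probe measured is uncertain.

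The 8 replicates were fitted with limma as 4 group means with a shared spread (4 residual degrees of freedom, 4.31 added by the empirical Bayes prior). CoPS and CoNS were each compared with healthy tissue as the equal-weight mean of both lactation groups against a ratio of 0. CoPS was compared with CoNS, later with earlier lactations, and the lactation difference in CoPS with that in CoNS, in the same fit. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01 between genes, over the 19906 genes with a value in every replicate, with adjustment over the 27 lists within a comparison. Members were matched by current or file name, so the endothelial list has 22 measured features for 21 listed genes. The lists covered antimicrobial proteins, acute phase proteins, pattern recognition and NF-kB signalling, cytokines, chemokines, interferon-stimulated genes, antigen presentation and complement. Cell type markers were those of neutrophils, monocytes and macrophages, T and NK cells, B and plasma cells, luminal epithelium, myoepithelium and smooth muscle, fibroblasts and extracellular matrix, adipocytes, endothelium, red blood cells, skeletal muscle and keratinised epithelium. The other lists covered milk proteins, milk fat synthesis, lactose synthesis with transport and lactogenic signalling, cell cycle, involution and apoptosis, immediate early with heat shock genes, and reference genes.

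Groups, tests, lists, named genes and most alternatives were fixed before the data were examined. For each of the 3 main comparisons the rule named, among genes with a symbol past the threshold and with the same sign in every replicate, the 10 highest and the 10 lowest log2 differences. For CoPS against CoNS the replicates of the 2 groups had to be free of overlap. It further named up to 4 members with the smallest p of each list past the camera threshold, and a fixed panel of milk, defence and fat synthesis genes. For the lactation comparisons it named the 5 highest and the 5 lowest. The panel gene M-SAA3.2 is not analysed here. Among the list members so named, 2 genes are counted but not reported here. Where a gene was well above background on no array of 1 of the samples compared, its change is given as a bound: the brighter sample's mean against, per array, the higher of the lowest signal well above background and the probe's own signal, after loess and Aquantile scaling.

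Tests were first run on data simulated from the 19906 genes with seeded changes. At a log2 change of 0.50, 98.4% of changed genes were recovered for CoPS and 98.7% for CoNS against healthy, 95.8% for CoPS against CoNS and 100% for later against earlier lactations. At 0.25 the shares were 79.4%, 82.3%, 45.3% and 42.6%, and false calls made up 9.31%, 5.05%, 8.48% and 7.65% of all calls. A list of 35 genes shifted by 0.25 in CoPS against CoNS was called in 20 of 20 simulated runs, and 3 unshifted lists were called over those runs. 100 simulations gave the correlation and covariance of CoPS and CoNS fold changes with no effect and a shared reference varying like the replicates.

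Alternatives fixed before the data were seen were no background subtraction, the scanner's own ratio, the authors' series table, median centring in place of loess, Aquantile scaling between arrays, no filter and a strict filter on dim probes, the mean over the probes of a gene, every probe by itself, and a trended robust variance. Further ones were all 16 arrays with the replicate as a random block, slide as a random block, lactation left out, replicates of the same bacteria alone, the replicate number as a block, an estimated correlation in camera, and leaving out each replicate. Chosen after seeing the data were the exchange of dye-swap partners between the 2 replicates of each CoPS group, the fit without both CoNS replicates 3, the comparison of CoPS with CoNS within each lactation group, slide as a random block for later against earlier lactations, list tests within lactation or bacteria groups, and list tests of the difference between lactation differences.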

Results

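The series profiled mammary gland tissue of Holstein Friesian cows (Bos taurus) with staphylococcal infection of the gland. Coagulase-positive staphylococci (CoPS, the class that includes Staphylococcus aureus) and coagulase-negative staphylococci (CoNS) are common causes of mastitis in dairy cows. Tissue infected with either class was split into lactations 1 and 2 or 3 and 4. This gave 4 groups of 2 pooled biological replicates, on 16 dye-swapped arrays. Pooled RNA of healthy tissue from lactations 1 to 4 was the reference on every array. The design asks how each infection differs from healthy tissue and from the other, and how later lactations differ from earlier ones.

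Between 59.9% and 75.4% of probes were well above background per channel on 14 arrays. The exceptions were the second array of CoNS replicate 3 in lactations 1 and 2, with 99.7% in Cy3 and 99.8% in Cy5, and the second array of CoNS replicate 4 in lactations 3 and 4, with 87.4% in Cy5. Log2 ratios of the 2 replicates correlated across genes at r = 0.974 and 0.977 in CoPS (lactations 1 and 2, then 3 and 4). In CoNS r was 0.844 and 0.876, and genes are not independent replicates. In both CoPS groups, single arrays differed in a way that the labelled averages cancelled. With second arrays exchanged between replicates, r was 0.613 and 0.864. The spread of the CoPS replicates, and the shared spread with it, depends on the pairing, so gene counts are also given with crossed partners. Group means do not change.

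**Figure D1:**
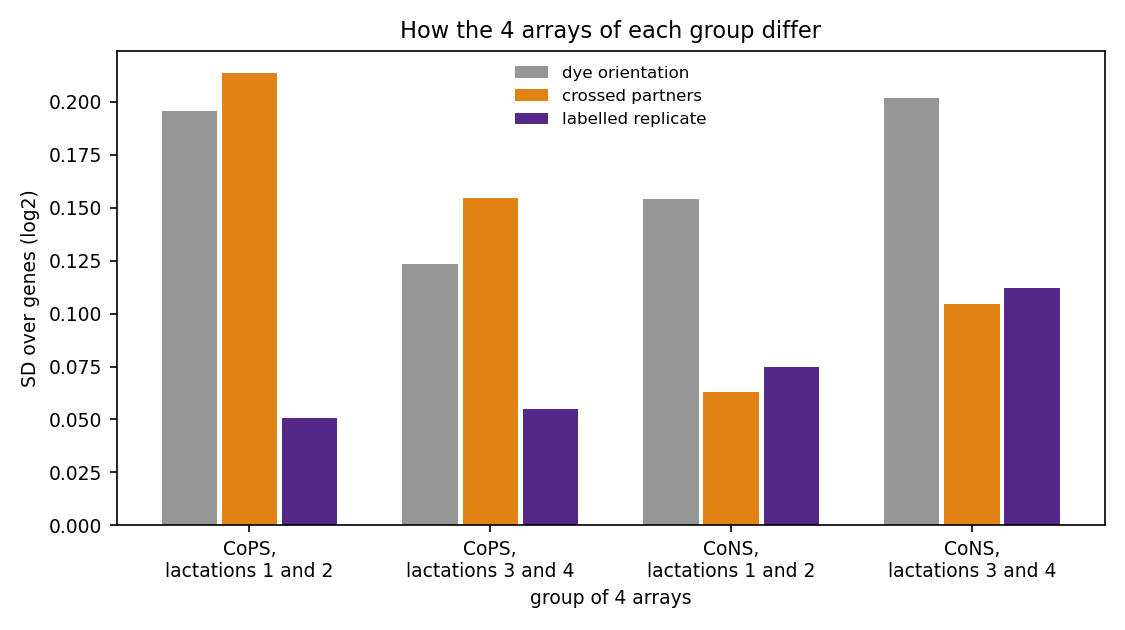
Standard deviation across 19906 genes of 3 parts of the array log2 ratios (y axis, log2) in each group (x axis): the dye part, the part that separates the labelled replicates and the part that separates replicates with crossed dye-swap partners. In the CoPS groups the crossed part is 0.21 and 0.15 and the labelled part 0.050 and 0.055, while in the CoNS groups they are 0.063 and 0.10 against 0.075 and 0.11.

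In CoPS-infected tissue, defence genes rose against healthy tissue, with acute phase and antimicrobial genes among the highest, and genes of milk synthesis fell. The highest gene with a symbol was HP, which encodes the haemoglobin scavenger haptoglobin, at 43.2-fold (log2 5.43 ± 0.20). Values with ± are log2 ratios with the standard error of the fit, n = 4 replicates per infection unless stated. That error comes from the spread between the replicates within each group. It leaves out the difference between the lactation groups of an infection, so replicates can lie much further apart. The acute phase gene SAA2 was 25.1-fold (log2 4.65 ± 0.081) and the beta-defensin LAP 23.3-fold (log2 4.54 ± 0.087) higher, and the chemokine CCL2 18.0-fold (log2 4.17 ± 0.16), all in 4 of 4 replicates. The calprotectin subunit S100A9, CFB, a complement activator, the beta-defensin TAP, IL1RN, the interleukin 1 receptor antagonist, VNN1 and CHODL completed the 10 highest, at 4.06 ± 0.21, 4.04 ± 0.034, 3.74 ± 0.22, 3.73 ± 0.18, 3.66 ± 0.22 and 3.61 ± 0.19. The lowest were ASB11 (-2.87 ± 0.032), the smooth muscle actin ACTG2 (-2.39 ± 0.071; 1 of its 2 other probes was called higher), STATH (-2.05 ± 0.082), a secreted calcium-binding protein gene near the caseins, and FST (-2.02 ± 0.040), followed by ACSM2B (-1.88 ± 0.063), PPARGC1A (-1.85 ± 0.072), KRT24 (-1.85 ± 0.063), SCGB1D (-1.78 ± 0.057), ME3 (-1.78 ± 0.10) and CFDP2 (-1.75 ± 0.085); 3 of the 5 other CFDP2 probes were called higher.

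Of the antimicrobial protein genes, 24 of the 31 measured rose and 5 fell (24 and 5 adjusted over the list alone). Their median log2 was 1.00 (camera adjusted p = 4.37e-06, adjusted p = 0.270 with an estimated correlation). S100A8, the other calprotectin subunit, rose by 3.52 ± 0.21 and S100A12 by 3.13 ± 0.056. Among the beta-defensins, DEFB4A, DEFB5 and DEFB10 rose by 2.97 ± 0.19, 2.44 ± 0.18 and 1.40 ± 0.067, and among the cathelicidins CATHL4 and CATHL1 rose by 0.84 ± 0.042 and 0.79 ± 0.051. LCN2 and LTF, whose proteins bind siderophores and iron, rose by 2.22 ± 0.040 and 1.33 ± 0.085, while the other LCN2 probe was called lower, and LPO, the milk peroxidase, was -1.18 ± 0.033. Of the acute phase genes, 11 of the 19 measured rose and 4 fell (11 and 5 adjusted over the list alone). They had a median log2 of 0.65 (camera adjusted p = 0.0135, adjusted p = 0.270 with an estimated correlation). SAA3, LBP and SERPINA3-3 rose by 3.56 ± 0.085, 1.44 ± 0.032 and 2.75 ± 0.076.

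Of the chemokines, 22 of the 31 measured rose and 5 fell (22 and 5 adjusted over the list alone), with a median log2 of 0.55, camera adjusted p = 6.67e-05, adjusted p = 0.270 with an estimated correlation. CCL20 rose at least 2.89-fold, and the chemokine receptor CXCR1, from the neutrophil list, at least 2.66-fold, since healthy tissue was not well above background. CXCL8 rose by 2.03 ± 0.20, CXCL14 by 1.08 ± 0.033 and CXCL16 by 0.93 ± 0.037. Of the cytokines, 13 of the 23 measured rose and 2 fell (13 and 2 adjusted over the list alone). Cytokine genes had a median log2 of 0.22 (camera adjusted p = 0.00544, adjusted p = 0.293 with an estimated correlation). TNF, IL1B and IL18 rose by 2.01 ± 0.089, 1.77 ± 0.12 and 1.17 ± 0.047, and IL6 at least 1.87-fold. TNFSF13B rose too, by an uncertain amount, as healthy tissue was well above background on 1 of 8 arrays. Of the pattern recognition and NF-kB genes, 15 of the 33 measured rose and 10 fell (15 and 10 adjusted over the list alone), and the list did not pass. They had a median log2 of 0.025 (camera adjusted p = 0.236). TLR4 and CD14, which bind lipopolysaccharide, rose by 0.62 ± 0.036 and 0.48 ± 0.030, whereas TLR2, a receptor of bacterial lipoproteins, was -0.45 ± 0.059 on its brightest probe and called higher on its 3 other probes.

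Leukocyte markers moved with these genes. Of the monocyte and macrophage markers, 17 of the 19 measured rose and 1 fell (17 and 1 adjusted over the list alone), with a median log2 of 1.18, camera adjusted p = 8.36e-07, adjusted p = 0.270 with an estimated correlation. C1QB (1.74 ± 0.039), C1QA (1.49 ± 0.041), VSIG4 (1.24 ± 0.049) and LAPTM5 (0.86 ± 0.033) rose. Of the neutrophil markers, 16 of the 24 measured rose and 5 fell (16 and 5 adjusted over the list alone), with a median log2 of 0.80, camera adjusted p = 0.00198, adjusted p = 0.406 with an estimated correlation. ITGB2 and CSF3R were 1.21 ± 0.053 and 0.79 ± 0.032. Of the T and NK cell markers, 22 of the 34 measured rose and 5 fell (22 and 5 adjusted over the list alone). They had a median log2 of 0.23 (camera adjusted p = 0.00144, adjusted p = 0.331 with an estimated correlation). NKG7, CD247 and CD96 were 1.20 ± 0.039, 0.89 ± 0.047 and 0.81 ± 0.043. B and plasma cell markers went both ways, 7 higher and 7 lower of 19 (7 and 7 adjusted over the list alone; median log2 0.0034, camera adjusted p = 0.558). Of the antigen presentation genes, 22 of the 25 measured rose and 1 fell (22 and 1 adjusted over the list alone). Their median log2 was 1.096 (camera adjusted p = 8.36e-07, adjusted p = 0.186 with an estimated correlation). They included BOLA-DQA2 (2.09 ± 0.068) and BOLA-DQA1 (1.92 ± 0.077), the protease CTSS (1.57 ± 0.070) and CD1E (1.15 ± 0.053). Of the interferon-stimulated genes, 25 of the 35 measured rose and 3 fell (25 and 3 adjusted over the list alone), with a median log2 of 0.43, camera adjusted p = 4.89e-06, adjusted p = 0.291 with an estimated correlation. MX1, OAS1Y, IFIT5 and GBP5 were 1.67 ± 0.062, 1.29 ± 0.061, 0.98 ± 0.043 and 0.69 ± 0.031. Of the complement genes, 21 of the 28 measured rose and 3 fell (21 and 3 adjusted over the list alone), with a median log2 of 0.81, camera adjusted p = 4.37e-06, adjusted p = 0.186 with an estimated correlation. C1S rose by 1.21 ± 0.036.

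All 12 measured milk protein genes fell (12 adjusted over the list alone), with a median log2 -1.02, camera adjusted p = 4.97e-06, adjusted p = 0.293 with an estimated correlation. LALBA, the alpha-lactalbumin subunit of lactose synthase, fell 2.83-fold, and the caseins CSN1S1, CSN2 and CSN3 were -1.03 ± 0.091, -0.90 ± 0.063 and -0.67 ± 0.082, in 4 of 4 replicates. GLYCAM1, MUC1 and MUC15 were -1.33 ± 0.084, -1.28 ± 0.058 and -0.99 ± 0.033. Of the milk fat synthesis genes, 5 of the 35 measured rose and 24 fell (5 and 24 adjusted over the list alone). They had a median log2 of -0.60 (camera adjusted p = 1.96e-04, adjusted p = 0.270 with an estimated correlation). FASN, the fatty acid synthase, and the desaturase SCD were -1.44 ± 0.13 and -1.33 ± 0.10. ACSS2, GPAM and ACSL1 were -1.13 ± 0.039, -1.06 ± 0.038 and -0.86 ± 0.031. Of the genes of lactose synthesis, transport and lactogenic signalling, 8 of the 28 measured rose and 18 fell (8 and 18 adjusted over the list alone), with a median log2 of -0.25, camera adjusted p = 0.0161, adjusted p = 0.270 with an estimated correlation. The amino acid transporters SLC7A5 and SLC1A5 were -1.58 ± 0.059 and -0.74 ± 0.031. The alveolar transcription factor ELF5 was -1.03 ± 0.043 and the hexokinase HK1 1.12 ± 0.039. Luminal epithelial markers had no such shift: 7 of the 21 measured rose and 10 fell (7 and 10 adjusted over the list alone). Their median log2 was -0.079 (camera adjusted p = 0.831), with a mean of 0.066 against the downward direction of the test. Monocyte and macrophage markers rose (median log2 1.18).

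Of the fibroblast and extracellular matrix genes, 22 of the 28 measured rose and 3 fell (22 and 3 adjusted over the list alone). Matrix genes had a median log2 of 0.52 (camera adjusted p = 3.55e-05, adjusted p = 0.186 with an estimated correlation). The collagens COL1A1 and COL1A2 were 1.40 ± 0.030 and 1.41 ± 0.045, MGP 1.34 ± 0.054 and FN1 0.87 ± 0.038; 1 of the 4 other COL1A1 probes was called lower. Of the cell cycle genes, 26 of the 31 measured rose and 1 fell (26 and 1 adjusted over the list alone). Cell cycle genes had a median log2 of 0.43 (camera adjusted p = 4.37e-06, adjusted p = 0.293 with an estimated correlation). MCM3, PCNA, MCM4 and MCM6, which act in DNA replication, were 0.99 ± 0.051, 0.89 ± 0.055, 0.82 ± 0.041 and 0.68 ± 0.031. Of the immediate early and heat shock genes, 22 of the 32 measured rose and 6 fell (23 and 6 adjusted over the list alone), with a median log2 of 0.51, camera adjusted p = 1.08e-04, adjusted p = 0.186 with an estimated correlation. FOS, EGR1, JUNB and HSP90AA1 were 2.40 ± 0.065, 1.98 ± 0.057, 1.31 ± 0.040 and 0.98 ± 0.032. Of the involution and apoptosis genes, 20 of the 30 measured rose and 5 fell (21 and 5 adjusted over the list alone), with a median log2 of 0.32, camera adjusted p = 0.00336, adjusted p = 0.270 with an estimated correlation. The chaperone CLU and the protease CTSB were 2.21 ± 0.085 and 0.86 ± 0.039, while IGFBP5 and CTSL were -0.87 ± 0.029 and -1.17 ± 0.044. Of the myoepithelial and smooth muscle markers, 4 of the 16 measured rose and 11 fell (4 and 11 adjusted over the list alone), with a median log2 of -0.53, camera adjusted p = 0.0159, adjusted p = 0.299 with an estimated correlation. CNN1, TPM2 and TAGLN were -0.99 ± 0.037, -0.74 ± 0.033 and -0.72 ± 0.030. Of the skeletal muscle genes, 1 of the 13 measured rose and 7 fell (1 and 7 adjusted over the list alone). Their median log2 was -0.12 (camera adjusted p = 0.0159, adjusted p = 0.270 with an estimated correlation). MYBPC1, CKM, MYH2 and ACTN2 were -1.13 ± 0.044, -0.79 ± 0.053, -0.74 ± 0.047 and -0.57 ± 0.038.

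The other lists did not pass. Of the endothelial markers, 5 of the 22 measured rose and 14 fell (5 and 14 adjusted over the list alone). Their median log2 was -0.22 (camera adjusted p = 0.120), although their mean was 0.050. Of the adipocyte markers, 5 of the 14 measured rose and 7 fell (5 and 7 adjusted over the list alone). They had a median log2 of -0.20 (camera adjusted p = 0.240). Of the keratinised epithelium genes, 6 of the 13 measured rose and 2 fell (6 and 2 adjusted over the list alone). Keratinised epithelium genes had a median log2 of 0.0017 (camera adjusted p = 0.241). Of the reference genes, 8 of the 20 measured rose and 3 fell (8 and 2 adjusted over the list alone). Reference genes had a median log2 of 0.046 (camera adjusted p = 0.153). Of the red blood cell genes, 2 of the 10 measured rose and 3 fell (2 and 3 adjusted over the list alone). Their median log2 was 0.0013 (camera adjusted p = 0.987).

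limma called 13477 of 20363 genes changed in CoPS against healthy, 6614 higher and 6863 lower, and 939 of them by at least 2-fold, 607 higher and 332 lower. With crossed partners 8433 genes were called, 8431 of them among the 13477, and 938 by at least 2-fold; all 104 named genes and all 19 list calls held. With labelled partners the 2-fold count was 2932 with the scanner's ratio and 1883 under median centring. With slide as a random block 7860 genes were called, and TLR2 and CATHL4 no longer passed. With each array centred on its median in place of loess, the median of all genes lay at 0.24, the share of calls that were higher was 68.7% in place of 49.1%, and the lists of cytokines, T and NK cell markers, lactose synthesis and myoepithelial markers were no longer called. Under that scaling the brightest TLR2 probe lay at 0.11 (limma adjusted p = 0.178), under that median, and the luminal epithelial median lay at 0.40, above it, while that of the milk proteins lay at -0.45 and the list stayed past the threshold (adjusted p = 1.71e-06). The probes of HP and LALBA lie on chromosome 18 at 38133540 to 38133599 and 5 at 34388762 to 34388821 (Btau_3.1).

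**Figure D2:**
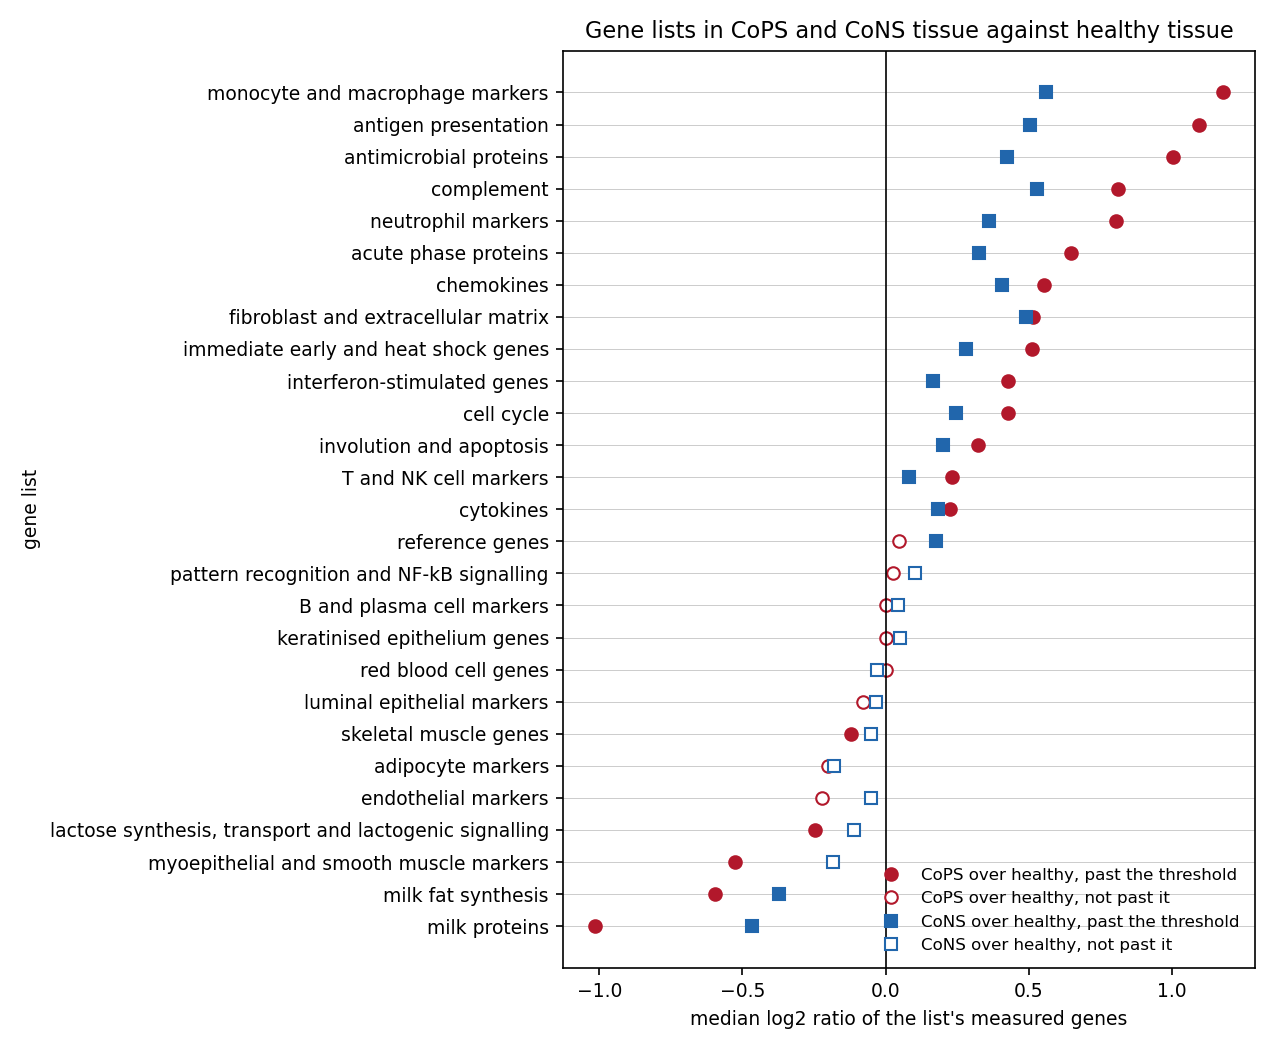
Median log2 ratio to healthy tissue (x axis, log2) of each of the 27 gene lists (y axis) in CoPS and in CoNS infection; filled points passed camera at adjusted p under 0.05 and open points did not. The milk protein list has the lowest median in both, -1.02 in CoPS and -0.47 in CoNS, and monocyte and macrophage markers the highest, 1.18 and 0.56.

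In CoNS-infected tissue acute phase, complement and antimicrobial genes were again among the highest. SAA2 was 10.3-fold (log2 3.37 ± 0.081) and SAA3 7.49-fold (log2 2.90 ± 0.085) higher than in healthy tissue, CFB 6.01-fold (log2 2.59 ± 0.034) and the superoxide dismutase SOD2 5.35-fold (log2 2.42 ± 0.032), each in 4 of 4 replicates. LAP, CHI3L1, IL1RN, FOS, CCL2 and CHODL followed at 2.30 ± 0.087, 2.27 ± 0.095, 2.23 ± 0.18, 2.22 ± 0.065, 2.18 ± 0.16 and 2.13 ± 0.19. STATH was the lowest at 4.80-fold (log2 -2.26 ± 0.082), then the class I gene BOLA-N (-2.01 ± 0.13; 2 of its 3 other probes were called higher), TMEM201 (-2.00 ± 0.12), ASB11 (-1.92 ± 0.032), SCGB1D (-1.84 ± 0.057), CFDP2 (-1.73 ± 0.085), RN18S1 (-1.62 ± 0.14), INHBC (-1.61 ± 0.18), FST (-1.59 ± 0.040) and KRT24 (-1.49 ± 0.063).

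Of the fibroblast and extracellular matrix genes, 24 of 28 rose and 3 fell (25 and 3 adjusted over the list alone). Matrix genes had a median log2 of 0.49 (camera adjusted p = 3.70e-10, adjusted p = 0.0648 with an estimated correlation). COL1A1, COL1A2, FN1 and BGN were 1.96 ± 0.030, 1.92 ± 0.045, 1.26 ± 0.038 and 1.02 ± 0.033, with 1 of the 4 other COL1A1 probes called lower. Of the complement genes, 21 of 28 rose and 3 fell (21 and 3 adjusted over the list alone), with a median log2 of 0.53, camera adjusted p = 1.72e-08, adjusted p = 0.105 with an estimated correlation. C1S rose by 0.82 ± 0.036. Of the antimicrobial genes, 18 of 31 rose and 6 fell (19 and 6 adjusted over the list alone). Antimicrobial genes had a median log2 of 0.43 (camera adjusted p = 4.60e-04, adjusted p = 0.300 with an estimated correlation). S100A12, S100A9, S100A8, TAP, DEFB4A, DEFB5 and DEFB10 were 2.09 ± 0.056, 2.05 ± 0.21, 1.98 ± 0.21, 1.98 ± 0.22, 1.47 ± 0.19, 1.19 ± 0.18 and 0.56 ± 0.067. LTF, LCN2 and LPO were 1.62 ± 0.085, 1.18 ± 0.040 and -0.67 ± 0.033, with the other LCN2 probe called lower, and CATHL1 was -0.27 ± 0.051, while CATHL4 at -0.017 ± 0.042 did not pass (limma adjusted p = 0.760). Of the acute phase genes, 10 of 19 rose and 3 fell (10 and 3 adjusted over the list alone). Acute phase genes had a median log2 of 0.33 (camera adjusted p = 0.00692, adjusted p = 0.256 with an estimated correlation). HP, SERPINA3-3 and LBP were 1.93 ± 0.20, 0.86 ± 0.076 and 0.66 ± 0.032; 1 of the 2 other SERPINA3-3 probes was called lower.

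Leukocyte markers save those of B and plasma cells moved likewise in CoNS over both lactation groups. In lactations 1 and 2 alone camera did not call the antigen presentation (median -0.042, camera adjusted p = 0.937), interferon-stimulated (-0.025, 0.937), T and NK cell (-0.016, 0.937) and neutrophil lists (0.087, 0.337). It called these in lactations 3 and 4 (adjusted p of at least 0.171 with an estimated correlation). Of the monocyte and macrophage markers, 16 of 19 rose and 2 fell (17 and 2 adjusted over the list alone), with a median log2 of 0.56, camera adjusted p = 1.00e-07, adjusted p = 0.300 with an estimated correlation. C1QB, C1QA, CTSS and C1QC were 1.27 ± 0.039, 0.98 ± 0.041, 1.05 ± 0.070 and 0.96 ± 0.069. Of the neutrophil markers, 15 of 24 rose and 4 fell (15 and 5 adjusted over the list alone), with a median log2 of 0.36, camera adjusted p = 0.00233, adjusted p = 0.429 with an estimated correlation. ITGB2 and NCF4 were 0.73 ± 0.053 and 0.54 ± 0.038, and ELANE at -0.56 ± 0.042 against 1 other probe called higher. Of the T and NK cell markers, 16 of 34 rose and 5 fell (16 and 5 adjusted over the list alone). They had a median log2 of 0.082 (camera adjusted p = 0.0126, adjusted p = 0.429 with an estimated correlation). NKG7 and CD8A were 0.59 ± 0.039 and 0.51 ± 0.056, and CD3D at -0.66 ± 0.052 against 1 of 2 other probes called higher. Of the chemokines, 22 of 31 rose and 5 fell (22 and 5 adjusted over the list alone), with a median log2 of 0.41, camera adjusted p = 7.31e-06, adjusted p = 0.256 with an estimated correlation. CXCL8 was 2.83-fold higher, and CXCL13, CXCL16 and CXCL14 were 0.65 ± 0.060, 0.50 ± 0.037 and 0.43 ± 0.033. Of the cytokines, 13 of 23 rose and 2 fell (13 and 3 adjusted over the list alone). They had a median log2 of 0.18 (camera adjusted p = 0.00146, adjusted p = 0.300 with an estimated correlation). IL1B, TNF and IL18 were 1.02 ± 0.12, 0.63 ± 0.089 and 0.44 ± 0.047; TNF and IL18 did not pass with crossed partners. IL6 and TNFSF13B rose too, by uncertain amounts, as healthy tissue was well above background on 1 and 2 of 8 arrays. Of the antigen presentation genes, 18 of 25 rose and 2 fell (18 and 3 adjusted over the list alone), with a median log2 of 0.51, camera adjusted p = 1.65e-05, adjusted p = 0.246 with an estimated correlation. BOLA-DQA2 and BOLA-DQA1 were 0.99 ± 0.068 and 0.89 ± 0.077. Of the interferon-stimulated genes, 21 of 35 rose and 4 fell (23 and 4 adjusted over the list alone), with a median log2 of 0.17, camera adjusted p = 5.49e-05, adjusted p = 0.324 with an estimated correlation. MX1, PARP14, IFI44 and DHX58 were 0.62 ± 0.062, 0.50 ± 0.041, 0.44 ± 0.041 and 0.34 ± 0.032. TLR4 and CD14 were 0.50 ± 0.036 and 0.38 ± 0.030, and the brightest TLR2 probe, against 2 of 3 others called higher, -0.20 ± 0.059.

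Of the 12 milk protein genes, 9 fell (11 adjusted over the list alone), with a median log2 -0.47, camera adjusted p = 9.62e-04, adjusted p = 0.419 with an estimated correlation, and in the authors' series table the list was not called (median -0.26, camera adjusted p = 0.106). MUC1, LALBA, MUC15 and MFGE8 fell, at -0.77 ± 0.058, -0.76 ± 0.083, -0.69 ± 0.033 and -0.50 ± 0.047, and CSN1S1 was -0.25 ± 0.091 (limma adjusted p = 0.0448), a call that ended with the authors' values and without any 1 replicate except CoNS replicate 3 of lactations 3 and 4. CSN2 at -0.17 ± 0.063 (limma adjusted p = 0.0542) and CSN3 at -0.015 ± 0.082 (adjusted p = 0.895) did not pass; without CoNS replicate 4 of lactations 3 and 4, CSN3 was higher at 0.14, the direction in which its other probe was called. Of the milk fat synthesis genes, 7 of 35 rose and 22 fell (7 and 22 adjusted over the list alone). Their median log2 was -0.37 (camera adjusted p = 0.00368, adjusted p = 0.334 with an estimated correlation). GPAM, PPARGC1A, AGPAT1, ACSL1, FASN and SCD were -1.35 ± 0.038, -1.22 ± 0.072, -0.77 ± 0.046, -0.65 ± 0.031, -0.51 ± 0.13 and -0.45 ± 0.10. Luminal epithelial markers had a median log2 -0.034, camera adjusted p = 0.469, with 6 higher and 6 lower (6 and 6 adjusted over the list alone), against an upward direction and a mean of 0.053.

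Of the cell cycle genes, 20 of 31 rose (21 adjusted over the list alone; median log2 0.25, camera adjusted p = 1.03e-07, adjusted p = 0.300 with an estimated correlation). UBE2C, MCM3, MCM4 and MCM6 were 0.58 ± 0.041, 0.59 ± 0.051, 0.45 ± 0.041 and 0.40 ± 0.031. Of the immediate early and heat shock genes, 24 of 32 rose and 5 fell (25 and 5 adjusted over the list alone), with a median log2 of 0.28, camera adjusted p = 3.70e-06, adjusted p = 0.0648 with an estimated correlation. HSPA1A, EGR1 and JUNB were 1.28 ± 0.052, 1.11 ± 0.057 and 0.70 ± 0.040. Of the involution genes, 17 of 30 rose and 4 fell (17 and 4 adjusted over the list alone), with a median log2 of 0.20, camera adjusted p = 4.28e-04, adjusted p = 0.246 with an estimated correlation. CLU, TGFB3, CTSB and IGFBP5 were 1.69 ± 0.085, 1.11 ± 0.056, 0.55 ± 0.039 and -0.37 ± 0.029. Of the reference genes, 9 of 20 rose and 1 fell (9 and 1 adjusted over the list alone). Reference genes had a median log2 of 0.18 (camera adjusted p = 0.00359, adjusted p = 0.419 with an estimated correlation). GAPDH, TUBA1A and HPRT1 were 0.83 ± 0.079, 0.81 ± 0.035 and 0.33 ± 0.052, and under median centring their median was -0.011 (adjusted p = 0.366). Replicate 3 of lactations 3 and 4 had the highest mean of the list, 0.57 against 0.10 to 0.17 in the others, and without it the median was 0.073 (camera adjusted p = 0.0280). The lists of lactose synthesis (median -0.11, camera adjusted p = 0.0647), myoepithelial markers (-0.18, adjusted p = 0.0722), adipocyte markers (-0.18, adjusted p = 0.0875), skeletal muscle (-0.050, adjusted p = 0.220), pattern recognition (0.10, adjusted p = 0.122), keratinised epithelium (0.050, adjusted p = 0.122), B and plasma cells (0.044, adjusted p = 0.157), endothelium (-0.051, adjusted p = 0.622) and red blood cells (-0.029, adjusted p = 0.807) did not pass.

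limma called 10686 genes changed in CoNS against healthy, 4731 higher and 5955 lower, and 202 by at least 2-fold, 136 higher and 66 lower. With crossed partners in CoPS, which widen the shared spread, 3726 genes were called, 200 of them by at least 2-fold, and the named genes IL18, MFGE8, IGFBP5, FASN, SCD, TNF, CATHL1, CSN1S1 and TLR2 no longer passed. With labelled partners the 2-fold count was 1102 with the scanner's ratio, 414 with no background subtraction, 343 in the authors' table and 308 without both CoNS replicates 3. With slide as a random block 2285 genes were called and 34 of the 97 named genes no longer passed, among them S100A9, CXCL8, IL1B, MUC1 and LALBA; with lactation left out 6227 were called. Fold changes were uneven: 176 genes changed at least 2-fold in lactations 1 and 2, and 642 in lactations 3 and 4. The counts were 139 and 612 with crossed partners, 521 and 3020 with the scanner's ratio. The array with nearly all probes above background belongs to lactations 1 and 2, where 6207 genes were called, 3226 without replicate 3, 3565 without replicate 4 and 866 with crossed partners.

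**Figure D3:**
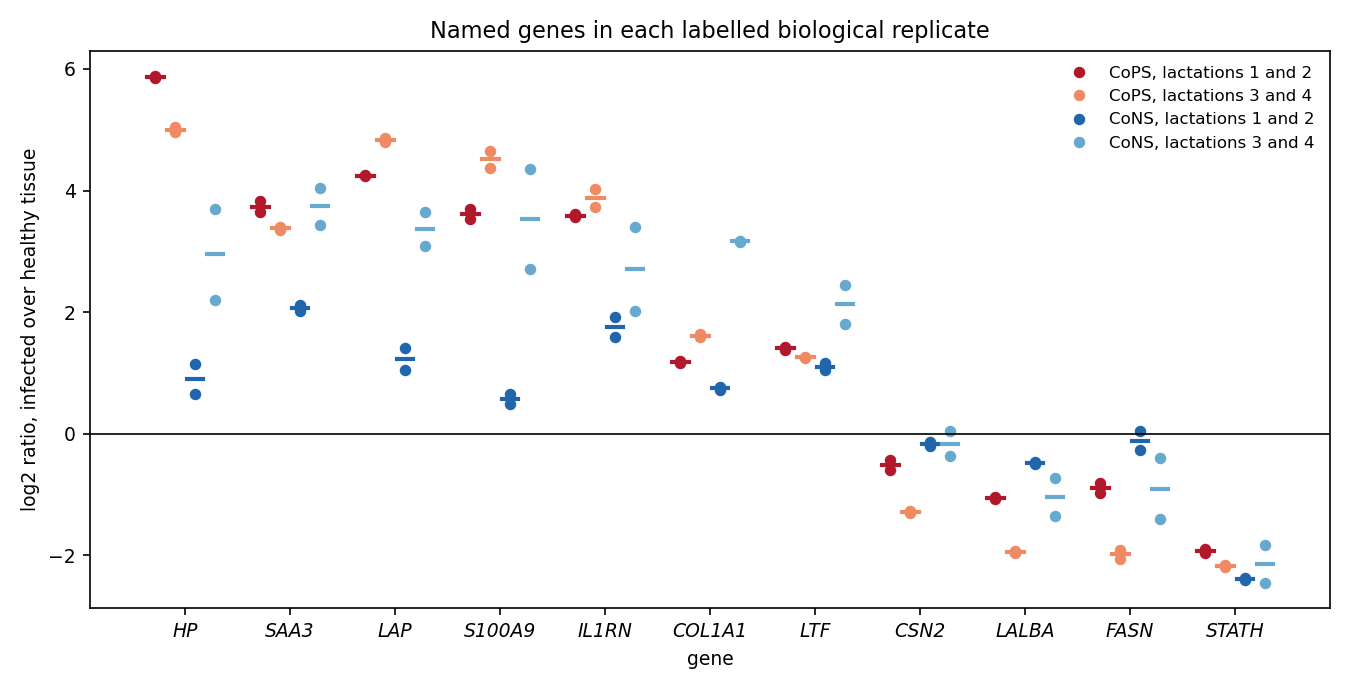
Log2 ratio of infected to healthy tissue (y axis, log2) of 11 named genes (x axis) in each of the 8 replicates (points) of the 4 groups, with group means as bars. HP means are 5.86 and 5.00 in CoPS and 0.90 and 2.95 in CoNS, for lactations 1 and 2 and lactations 3 and 4, while LALBA lies below 0 in every group.

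Averaged over lactations, CoPS-infected tissue exceeded CoNS-infected tissue in most defence lists, although no defence list passed as higher in lactations 3 and 4, the comparison within 1 scan. With an estimated correlation camera called 0 of the 27 lists, the lowest adjusted p being 0.264, with 4 lists at an unadjusted p under 0.05. The milk protein list was lower after loess normalisation and not called after median centring. HP was 11.4-fold (log2 3.51 ± 0.28) higher in CoPS, LAP 4.72-fold (log2 2.24 ± 0.12) and the acute phase protease inhibitor SERPINA3-3 3.69-fold (log2 1.89 ± 0.11). The 4 CoPS and 4 CoNS replicates did not overlap, as the naming rule required. The class I genes BOLA-N and JSP.1 were 3.17 ± 0.18 and 2.91 ± 0.078, and CFI, RGS4, CXCL5, FOXA3 and GPNMB 1.99 ± 0.17, 1.89 ± 0.16, 1.70 ± 0.18, 1.70 ± 0.10 and 1.69 ± 0.070. Lower in CoPS were CYP1A1 (2.94-fold, log2 -1.56 ± 0.057), BDA20, a lipocalin allergen gene, (-1.49 ± 0.069), ACTG2 (-1.41 ± 0.10), SLPI (-1.40 ± 0.20), H4 (-1.05 ± 0.094), GADD45G (-1.03 ± 0.051), MYH2 (-1.02 ± 0.067), INHBA (-0.99 ± 0.067), PSPH (-0.98 ± 0.057) and C1QTNF9 (-0.97 ± 0.080); the other SLPI probe was called higher.

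Of the antimicrobial genes, 22 of 31 rose and 3 fell (23 and 4 adjusted over the list alone). They had a median log2 of 0.84 (camera adjusted p = 2.09e-06, adjusted p = 0.264 with an estimated correlation). CATHL1, CATHL2, CATHL3, CATHL4, S100A12 and LCN2 were 1.06 ± 0.073, 0.93 ± 0.059, 0.88 ± 0.058, 0.86 ± 0.059, 1.05 ± 0.079 and 1.04 ± 0.057. S100A9, TAP, S100A8, DEFB4A, DEFB5 and DEFB10 were 2.02 ± 0.30, 1.76 ± 0.31, 1.54 ± 0.30, 1.49 ± 0.27, 1.25 ± 0.25 and 0.84 ± 0.094. With crossed partners 3 antimicrobial genes stayed past the threshold, namely LAP, LCN2 and S100A12, although the other LCN2 probe was called lower. Of the acute phase genes, 10 of 19 rose and 2 fell (11 and 2 adjusted over the list alone). Acute phase genes had a median log2 of 0.20 (camera adjusted p = 0.00233, adjusted p = 0.264 with an estimated correlation). LBP, ITIH4 and SAA3 were 0.78 ± 0.045, 0.75 ± 0.061 and 0.65 ± 0.12. Of the antigen presentation genes, 16 of 25 rose (17 and 1 adjusted over the list alone; median log2 0.48, camera adjusted p = 1.89e-06, adjusted p = 0.264 with an estimated correlation). BOLA-DQA2 was 2.14-fold higher, and BOLA-DQA1 and PSMB10 were 1.03 ± 0.11 and 0.59 ± 0.061. Of the complement genes, 13 of 28 rose and 2 fell (15 and 4 adjusted over the list alone), with a median log2 of 0.33, camera adjusted p = 0.00213, adjusted p = 0.264 with an estimated correlation. CFB and SERPING1 were 1.45 ± 0.048 and 0.66 ± 0.071. Of the interferon-stimulated genes, 19 of 35 rose and 2 fell (20 and 3 adjusted over the list alone), with a median log2 of 0.21, camera adjusted p = 1.40e-04, adjusted p = 0.373 with an estimated correlation. MX1, OAS1Y, IFIT5 and GBP5 were 1.05 ± 0.087, 0.76 ± 0.086, 0.60 ± 0.061 and 0.55 ± 0.044.

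Leukocyte markers differed too, save those of B and plasma cells (median 0.00033). Of the monocyte and macrophage markers, 15 of 19 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 of 0.52, camera adjusted p = 1.89e-06, adjusted p = 0.292 with an estimated correlation. VSIG4, C1QA, LAPTM5 and C1QB were 0.68 ± 0.069, 0.51 ± 0.057, 0.50 ± 0.047 and 0.47 ± 0.055. Of the neutrophil markers, 15 of 24 rose and 3 fell (17 and 3 adjusted over the list alone), with a median log2 of 0.37, camera adjusted p = 8.98e-04, adjusted p = 0.429 with an estimated correlation. CXCR1, ALOX5AP and CSF3R were 0.87 ± 0.083, 0.75 ± 0.10 and 0.56 ± 0.045. Of the T and NK cell markers, 13 of 34 rose and 1 fell (14 and 1 adjusted over the list alone). They had a median log2 of 0.11 (camera adjusted p = 0.00297, adjusted p = 0.427 with an estimated correlation). The call ended under median centring (adjusted p = 0.9998). NKG7, CD96 and CD7 were 0.60 ± 0.056, 0.55 ± 0.061 and 0.41 ± 0.048. Of the chemokines, 14 of 31 rose and 2 fell (15 and 2 adjusted over the list alone), with a median log2 of 0.20, camera adjusted p = 0.00581, adjusted p = 0.373 with an estimated correlation. CCL20 was 2.14-fold higher, and CCL19 and CXCL14 were 1.20 ± 0.13 and 0.66 ± 0.047. Of the panel, TNF and IL1B were 1.38 ± 0.13 and 0.76 ± 0.17, and IL1B no longer passed without replicate 1 of either CoPS group or CoNS replicate 3 of lactations 1 and 2. CXCL8 (0.53 ± 0.28, limma adjusted p = 0.187), CD14 (0.10 ± 0.042, 0.124), TLR4 (0.12 ± 0.051, 0.113), LTF (-0.29 ± 0.12, 0.105) and TLR2 (-0.25 ± 0.084, 0.0507) did not pass.

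Of the 12 milk protein genes, 11 fell (11 adjusted over the list alone; median log2 -0.70, camera adjusted p = 3.33e-07, adjusted p = 0.292 with an estimated correlation). CSN1S2, GLYCAM1, CSN1S1, LALBA, CSN2, CSN3 and MUC15 were -0.83 ± 0.11, -0.79 ± 0.12, -0.77 ± 0.13, -0.74 ± 0.12, -0.73 ± 0.089, -0.66 ± 0.12 and -0.31 ± 0.046; with crossed partners limma called 0 of the 12, with 11 lower at an unadjusted p under 0.05. Median centring moved genes by different amounts: the median of all genes became 0.31, these 7 became positive, and the list median, at 0.24, lay close to that of all genes (adjusted p = 0.962). Of the milk fat genes, 6 of 35 rose and 16 fell (6 and 19 adjusted over the list alone). They had a median log2 of -0.21 (camera adjusted p = 6.95e-04, adjusted p = 0.296 with an estimated correlation). FASN, SCD, SLC27A6 and ACSS2 were -0.93 ± 0.19, -0.88 ± 0.14, -0.57 ± 0.063 and -0.56 ± 0.055, which became positive there (list median 0.39), and DGAT2 and ACLY were 0.77 ± 0.080 and 0.52 ± 0.065. Of the lactose synthesis and transport genes, 3 of 28 rose and 9 fell (3 and 12 adjusted over the list alone). Lactose synthesis and transport genes had a median log2 of -0.13 (camera adjusted p = 0.00776, adjusted p = 0.264 with an estimated correlation), and 0.40 under median centring. AQP3, SLC39A8, HK1 and PRLR were -0.80 ± 0.068, -0.43 ± 0.048, 0.59 ± 0.056 and 0.43 ± 0.061, SLC39A8 becoming positive there. Of the matrix genes, 3 of 28 rose and 9 fell (4 and 12 adjusted over the list alone). Matrix genes had a median log2 of -0.15 (camera adjusted p = 0.00297, adjusted p = 0.264 with an estimated correlation), and 0.42 under median centring. COL1A1, COL1A2 and BGN were -0.56 ± 0.043, -0.51 ± 0.063 and -0.40 ± 0.047, which became positive, and MGP was 0.69 ± 0.077. Of the myoepithelial markers, 3 of 16 rose and 10 fell (4 and 11 adjusted over the list alone), with a median log2 of -0.26, camera adjusted p = 0.00233, adjusted p = 0.292 with an estimated correlation, and 0.47 under median centring. CNN1 and TPM2 were -0.76 ± 0.052 and -0.59 ± 0.046, which became positive, and the basal keratin KRT14 was 0.77 ± 0.050.

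Of the cell cycle genes, 11 of 31 rose (12 adjusted over the list alone; median log2 0.13, camera adjusted p = 0.0244, adjusted p = 0.580 with an estimated correlation), among them PCNA (0.53 ± 0.078), MCM5 (0.38 ± 0.048), MCM4 (0.37 ± 0.057) and MCM6 (0.28 ± 0.044); under median centring the list lay at 0.20, below the median of all genes, and without CoNS replicate 3 of lactations 1 and 2 or of lactations 3 and 4 it was 0.10 and 0.042 and not called (camera adjusted p = 0.0513 and 0.130). Of the immediate early and heat shock genes, 14 of 32 rose and 2 fell (14 and 2 adjusted over the list alone), with a median log2 of 0.11, camera adjusted p = 0.0198, adjusted p = 0.264 with an estimated correlation. EGR1, JUNB, HSPH1 and HSP90AA1 were 0.87 ± 0.081, 0.61 ± 0.056, 0.60 ± 0.060 and 0.47 ± 0.045. Of the skeletal muscle genes, 1 of 13 rose and 6 fell (1 and 6 adjusted over the list alone). Their median log2 was -0.064 (camera adjusted p = 0.00781, adjusted p = 0.292 with an estimated correlation). MYBPC1, CKM and ACTN2 were -0.48 ± 0.063, -0.41 ± 0.075 and -0.29 ± 0.053, CKM becoming positive under median centring. The cytokine list (8 of 23 higher; median 0.056, camera adjusted p = 0.0611) and the pattern recognition list (9 of 33 higher, 3 lower; 0.064, adjusted p = 0.262) did not pass, nor did the 8 other lists (lowest adjusted p = 0.203).

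limma called 6227 genes in CoPS against CoNS, 3800 higher and 2427 lower in CoPS, and 137 by at least 2-fold; the share of calls that were higher was 61.0%, and 83.9% under median centring. With crossed partners 295 genes were called, 65 of them by at least 2-fold; with labelled partners these were 1007 under median centring and 426 with the scanner's ratio. Of the named genes 35 still passed, HP among them, and 61 no longer did, while the 17 list calls stayed, with at most 5 members of any list past the threshold. With lactation left out 637 genes were called. With slide as a random block 19 were called, GADD45G (adjusted p = 0.0411) and KRT14 (adjusted p = 0.0484) being the only ones among the named genes. Without replicate 1 or 2 of CoPS lactations 1 and 2, or replicate 1 of CoPS lactations 3 and 4, the count was 3920, 3869 and 3579. Scan 1 held only CoPS, so the comparison within scan 2 is that of lactations 3 and 4, where 1500 genes differed (11 with crossed partners), 826 higher and 674 lower in CoPS. There the milk proteins (median -0.90, camera adjusted p = 3.48e-10), the matrix genes (-0.36, 5.12e-09), the milk fat genes (-0.12, 4.75e-04) and markers of B and plasma cells (-0.058, 0.00874), endothelium (-0.21, 0.0141) and myoepithelium (-0.21, 0.0230) were lower, while the antimicrobial (0.31, 0.0569), macrophage (0.21, 0.0569), antigen presentation (0.14, 0.0569), acute phase (0.087, 0.0920), neutrophil (0.024, 0.766), chemokine (0.0024, 0.933) and complement lists (0.013, 0.987) did not pass. In lactations 1 and 2, across scans, 6466 genes differed (169 with crossed partners), and the antimicrobial (median 1.34, camera adjusted p = 7.35e-08), antigen presentation (0.91, 7.35e-08), macrophage (0.83, 7.35e-08) and complement lists (0.69, 2.24e-05) were higher in CoPS, and the milk protein (-0.48, 1.29e-04) and milk fat lists (-0.21, 0.0227) lower. With an estimated correlation camera called 0 lists in either, the lowest adjusted p being 0.150 and 0.220, and 2 and 5 lists had an unadjusted p under 0.05.

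In later lactations, averaged over both infections, markers of macrophages, antigen presentation and interferon response were higher than in earlier ones. Milk protein and adipocyte genes were lower. The pooled healthy reference cancels here, so lactation differences of healthy tissue are not removed. The neutrophil protein gene S100A12 was 5.86-fold (log2 2.55 ± 0.079) and the copper carrier CP 4.19-fold (log2 2.07 ± 0.24) higher than in earlier lactations, followed by the immunoglobulin constant gene IgCgamma, NOS2, which makes nitric oxide, and GRP, at 1.87 ± 0.19, 1.80 ± 0.27 and 1.79 ± 0.044 (n = 4 replicates each). SHISAL2B was 3.98-fold lower (log2 -1.99 ± 0.13), then SCGB1D (-1.96 ± 0.080), CPXM2 (-1.65 ± 0.10), TTC36 (-1.64 ± 0.12) and RRAD (-1.62 ± 0.11). Of the monocyte and macrophage markers, 16 of 19 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 of 0.46, camera adjusted p = 2.39e-06, adjusted p = 0.314 with an estimated correlation. Of the antigen presentation genes, 19 of 25 rose and 3 fell (20 and 3 adjusted over the list alone), with a median log2 of 0.50, camera adjusted p = 5.26e-06, adjusted p = 0.252 with an estimated correlation. Of the interferon-stimulated genes, 24 of 35 rose and 2 fell (25 and 2 adjusted over the list alone), with a median log2 of 0.28, camera adjusted p = 9.20e-07, adjusted p = 0.314 with an estimated correlation. Of the complement genes, 17 of 28 rose and 1 fell (19 and 2 adjusted over the list alone), with a median log2 of 0.44, camera adjusted p = 6.38e-06, adjusted p = 0.252 with an estimated correlation. Of the milk protein genes 11 of 12 fell (11 adjusted over the list alone; median log2 -0.57, camera adjusted p = 4.32e-06, adjusted p = 0.339 with an estimated correlation), of the adipocyte markers 10 of 14 (10 adjusted over the list alone; median log2 -0.32, camera adjusted p = 6.40e-06, adjusted p = 0.252 with an estimated correlation) and of the milk fat genes 15 of 35, with 4 higher (4 and 16 adjusted over the list alone; median log2 -0.24, camera adjusted p = 2.09e-04, adjusted p = 0.314 with an estimated correlation). T and NK cell markers (median 0.11, camera adjusted p = 0.00538), B and plasma cell markers (0.12, 0.0260), matrix genes (0.15, 0.0353) and cell cycle genes (0.11, 0.00617) were higher, and genes of lactose synthesis (-0.19, 0.00204), myoepithelium (-0.25, 0.00448) and skeletal muscle (-0.13, 0.00617) lower, each with an adjusted p of at least 0.252 with an estimated correlation. The matrix call ended under median centring (adjusted p = 0.219) and without CoNS replicate 3 of lactations 1 and 2 (0.0774), where that of the B and plasma cell list ended too, and the cell cycle call ended without CoNS replicate 4 of lactations 3 and 4 (0.0542).

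limma called 6588 genes in this comparison, 3654 higher and 2934 lower in later lactations, and 179 by at least 2-fold. With crossed partners 1069 genes were called, 159 by at least 2-fold (without crossing 1304 with the scanner's ratio, 458 with no background subtraction and 54 with slide as a random block), and all 10 named genes and 14 list calls held. With slide as a random block, which leaves out the bacteria, 281 genes were called, and GRP, SHISAL2B, SCGB1D, CPXM2 and RRAD stayed past the threshold. Within scan 2 the comparison is that of CoNS, where 6276 genes changed (638 with crossed partners), and the macrophage (median 0.82, camera adjusted p = 9.63e-08), antigen presentation (0.73, 3.35e-07) and complement lists (0.79, 1.05e-07) rose, while milk proteins (-0.30, 0.00136) and adipocyte markers (-0.23, 7.93e-04) fell. In CoPS, across scans, 2815 genes changed (58 with crossed partners), with milk proteins (median -0.71, camera adjusted p = 2.39e-07) and adipocyte markers (-0.43, 1.24e-06) lower and macrophage markers (0.14, 0.0226), antigen presentation (0.21, 0.0226) and complement (0.10, 0.0430) higher, while the lists of T and NK cells (-0.025, 0.960), B and plasma cells (0.010, 0.850), matrix (-0.019, 0.501) and cell cycle (-0.049, 0.159) passed in CoNS alone. With an estimated correlation camera called 0 lists in either, the lowest adjusted p being 0.190 in CoNS and 0.454 in CoPS, and 5 and 1 lists had an unadjusted p under 0.05. The CoPS count was 707 to 869 when any 1 of the 4 CoPS replicates was left out, and 4730 or 4723 without CoNS replicate 3 or 4 of lactations 3 and 4.

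The lactation difference, later minus earlier, itself differed between the infections in 1211 genes by limma, 948 of them lower in CoPS than in CoNS and 263 higher. HP was -2.92 ± 0.55 (CoPS log2 5.86 in lactations 1 and 2 and 5.00 in lactations 3 and 4, CoNS 0.90 and 2.95), S100A12 -3.28 ± 0.16 (2.68 and 3.59, -0.0090 and 4.18), CXCL8 -3.08 ± 0.55 (2.59 and 1.47, 0.52 and 2.48) and VNN1 -4.09 ± 0.70. The class II gene BOLA-DQA3 stood at log2 5.85 in CoPS lactations 1 and 2 and between -0.055 and 0.0078 in the other groups (-5.88 ± 0.11), and IGFLR1, JSP.1, BOLA-N, RAB5C and PON3 were the highest, at 2.42 ± 0.15, 2.00 ± 0.16, 1.98 ± 0.37, 1.55 ± 0.20 and 1.41 ± 0.11. With crossed partners 4 genes passed (adjusted p between 0.00576 and 0.0173), namely BOLA-DQA3, LOC790858, PTGDS and SOD2, of which the last 3 were chosen after their values were seen. The calls of HP, CXCL8 and BOLA-N ended without any 1 CoPS replicate or either CoNS replicate of lactations 1 and 2, that of VNN1 without any 1 CoPS replicate, and that of RAB5C without replicate 2 of CoPS lactations 3 and 4. The count was between 103 and 188 without any 1 CoPS replicate, 273 and 554 without CoNS replicate 3 or 4 of lactations 1 and 2, 3961 without CoNS replicate 3 of lactations 3 and 4, and 4323 without both CoNS replicates 3; under median centring, with the median of all genes at 0.24, 94.4% of the calls were higher in place of 21.7%. Slide, scan and group are not separable in this comparison.

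Fold changes against healthy tissue correlated between CoPS and CoNS across the 20363 genes (Pearson r = 0.872, Spearman rho = 0.823), although genes are not independent replicates. Both share the healthy reference, and simulated unchanged infections against a shared reference gave r = 0.800. The covariance was 0.114, against 0.00901 in the simulation and 0.0407 with a wider simulated spread, where r was again 0.800. Genes higher in both numbered 4058, against 1537 for independent lists, genes lower in both 4760, against 2007, and 252 were called in opposite directions. The reference is a single pool that cannot be split, so part of the excess may come from it.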

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

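The tests that weigh explanations here, the list tests of the difference between lactation differences and the exchange of dye-swap partners were chosen only after the results were seen.

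Of 415 groups of 4 values compared, 11 held a value far from the other 3, and chance gives about 1 in 20. The second array of CoNS replicate 3 in lactations 1 and 2 stood apart from the other arrays of its slide in the share of probes well above background, 99.7% in Cy3 and 99.8% in Cy5, and in the slope of measured on designed spike-in ratios, 0.762. Among the 4 CoNS replicates, replicate 4 of lactations 3 and 4 was apart in SCD (log2 ratio to healthy -0.997), CSN1S1 (-0.75), CSN1S2 (-0.57), CSN3 (-0.47) and GADD45G (0.024). Replicate 3 of the same group was apart in STATH (-1.82) and in its mean over the reference genes (0.57). Among the CoPS replicates, replicate 1 of lactations 1 and 2 was apart in TLR4 (0.50).

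The lactation difference of CoPS minus that of CoNS passed limma's test in 1211 genes and in 16 lists by camera, and with crossed partners in 4 genes. The list medians (log2) were antimicrobial proteins -0.84, acute phase proteins -0.49, cytokines -0.078, chemokines -0.39, neutrophil markers -0.48, monocyte and macrophage markers -0.63, T and NK cell markers -0.28, B and plasma cell markers -0.23, antigen presentation -0.60, interferon-stimulated genes -0.28, complement -0.68, fibroblast and extracellular matrix -0.52, endothelial markers -0.14, cell cycle -0.39, involution and apoptosis -0.28 and immediate early and heat shock genes -0.33. With an estimated correlation camera called 0 of the 27 lists, 6 having an unadjusted p under 0.05. Among named genes the difference (log2) was largest in BOLA-DQA3 -5.88, VNN1 -4.09, S100A12 -3.28, CXCL8 -3.08, HP -2.92, CCL2 -2.87, NOS2 -2.79, SAA2 -2.54, RN18S1 -2.34, CHODL -2.29, RGS4 -2.25 and SAA3 -2.03. Smaller negative differences were COL1A2 -1.99, COL1A1 -1.99, IgCgamma -1.90, CFI -1.82, SOD2 -1.81, IL6 -1.81, TNF -1.72, LCN2 -1.66, CHI3L1 -1.64, LAP -1.54, SERPINA3-3 -1.47, CCL19 -1.38, GPNMB -1.35, CTSS -1.27, NCF4 -1.24 and HSPA1A -1.22. Next came CCL20 -1.17, LTF -1.17, FOXA3 -1.17, CXCR1 -1.15, H4 -1.14, ACSS2 -1.11, SERPING1 -1.05, RRAD -1.04, DEFB10 -1.03, CLU -1.02, CATHL4 -1.01, FOS -0.996, CATHL3 -0.92, ASB11 -0.87, LAPTM5 -0.85, FN1 -0.84, CATHL2 -0.84, MCM3 -0.83 and CD3D -0.81. The remaining negative ones were TNFSF13B -0.79, GRP -0.79, VSIG4 -0.79, CSN2 -0.78, C1S -0.77, ITIH4 -0.76, FST -0.72, CD8A -0.71, C1QB -0.71, IL18 -0.68, JUNB -0.67, CFB -0.66, HSPH1 -0.66, CD96 -0.65, UBE2C -0.65, CYP1A1 -0.62, PSMB10 -0.62, LBP -0.60, C1QA -0.60, NKG7 -0.57, MCM6 -0.52, IGFBP5 -0.46, BGN -0.46 and CSF3R -0.40. Positive differences were IGFLR1 2.42, JSP.1 2.00, BOLA-N 1.98, RAB5C 1.55, PON3 1.41, BDA20 1.03 and AGPAT1 0.55.

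In both CoPS groups the labelled replicates were nearly identical while their dye-swapped arrays differed: the part of the array ratios that cancels in the labelled averages had an SD of 0.214 and 0.155, against 0.0505 and 0.0552 for the part that separates the labelled replicates. Array position on the slide is argued against by a correlation of only 0.0658 across genes of the cancelled part between both CoPS slides, and noise of dim spots by a ratio of the SDs of 5.31 among the brightest 6636 genes of lactations 1 and 2, above 4.23 over all genes. What stays open is that dye-swap partners were crossed between the replicates: the lower of the CoPS ratios was 2.81, while the CoNS ratios were 0.845 and 0.933. If so, the spread of the CoPS replicates may be understated in every count of genes, whereas the group means would not move. No biological explanation was tested, because the design gives no groups within the replicates.

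Fold changes were smaller in CoNS lactations 1 and 2 than in CoNS lactations 3 and 4, with 176 against 642 genes changed at least 2-fold and an SD of the replicate log2 ratios of 0.267 and 0.268 against 0.374 and 0.459. Compression of ratios on the array with nearly all probes above background is argued against as the whole cause, because the replicate of that group without this array had the SD of 0.268. Each slide held 1 group, so slide and group cannot be told apart. A weaker response, another course of infection or a lactation difference of healthy tissue, pooled over lactations, stays open and was not tested.

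Milk protein genes lay lower in CoPS than in healthy tissue (median log2 -1.02, median absolute deviation 0.278), while luminal epithelial markers had a median of -0.079 (0.585). An even loss of epithelial cells would lower both lists alike. The luminal median lay 0.937 above the milk protein median, which argues against that loss as the whole cause. Under median centring the luminal median was 0.40 and the milk protein median -0.45. Part of the fall could still come from dilution by leukocytes. Uneven loss of epithelial cells and lower expression of milk genes within them are untested hypotheses.

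Of the 35 ways to split the 8 replicates into 4 and 4, with lactation left out of the model, 2 gave at least the 637 genes of CoPS against CoNS, the highest other being the split by lactation with 2083. For later against earlier lactations, 1 of the 35 splits gave as many genes, the real one with 2083, and the highest other was 637. With crossed partners these counts were 9 and 161. Only 3 of the splits keep slides whole, which is too few for a share under 0.05, and the within-slide correlation was 0.576, so the structure that the splits show is also that of the slides.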

How the results depend on the processing

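The crossing of dye-swap partners, the fit without both CoNS replicates 3, slide as a random block for the lactation comparison and the alternatives for the correlation of fold changes were chosen only after the results were seen; the others were planned. Over all settings 7139 values of named genes kept their direction and their side of the threshold, 374 fell short of it, 22 newly passed, 8 changed sign with no call either way, and 27 changed sign with a call. For the lists the numbers were 1753, 87, 52, 45 and 7. The cause was not tested, except where the setting itself shows it. The strict filter on dim probes left 15252 genes.

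With crossed partners the counts were 8433 for CoPS against healthy, 3726 for CoNS against healthy, 295 for CoPS against CoNS, 1069 for later against earlier lactations and 4 for the difference between lactation differences. They were 4610 and 5239 for CoPS lactations 1 and 2 and lactations 3 and 4 against healthy, 866 and 3121 for the same CoNS groups, and 58 and 638 for later against earlier lactations in CoPS and in CoNS. The wider shared spread is the cause, since group means are the same. With slide as a random block they were 7860, 2285, 19 and 281 for the first 4. With lactation left out, which puts the lactation differences into the spread, CoNS against healthy gave 6227 and CoPS against CoNS 637. Testing every probe gave 21357 and 16708 probes against healthy in CoPS and CoNS, more features being tested. At least 2-fold, the mean over probes gave 133, 80 and 116 genes for CoNS against healthy, CoPS against CoNS and later against earlier lactations, and every probe 312 for CoNS against healthy. For CoPS against CoNS the 2-fold count was 87 without both CoNS replicates 3, 50 with lactation left out and 9 with slide as a random block.

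For later against earlier lactations, no background subtraction gave 10728 and the scanner's ratio 10023 genes. For the difference between lactation differences these gave 3068 and 1887, the authors' own values 568, median centring 7101 and leaving out both CoNS replicates 3 gave 4323. For CoPS later against earlier lactations the scanner's ratio gave 5354, the fit without both CoNS replicates 3 gave 6131 and CoPS replicates alone 6161. CoNS replicates alone gave 3112 for lactations 1 and 2 against healthy and 3097 for later against earlier lactations. Median centring gave 13394 for CoPS against CoNS. The correlation between CoPS and CoNS fold changes was 0.905 with no background subtraction, 0.649 under median centring and 0.903 without both CoNS replicates 3. With an estimated correlation camera called 0 lists in each of the 4 comparisons, with 4, 5, 4 and 4 lists at an unadjusted p under 0.05.

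Replicate numbers are shared by the lactation groups of an infection, but no label says what they share, and deviations of same-numbered replicates correlated at 0.178 in CoPS and 0.407 in CoNS, 2 pairs each. With the replicate number as a block the counts were 7657 for later against earlier lactations, 2467 for the difference between lactation differences, 4031 in CoPS and 7447 in CoNS.

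Leaving out 1 replicate at a time, where a lone replicate is assumed to vary like the other groups, gave 11364 to 14198 genes for CoPS against healthy, 8808 to 10501 for CoNS against healthy, 3579 to 8421 for CoPS against CoNS, 4610 to 7792 for later against earlier lactations, 103 to 3961 for the difference between lactation differences. Ranges were 7231 to 12078 and 7940 to 12373 for CoPS lactations 1 and 2 and lactations 3 and 4 against healthy, 3226 to 8093 and 8205 to 10169 for the same CoNS groups. They were 707 to 4730 and 4460 to 7384 for later against earlier lactations in CoPS and in CoNS, and 0.810 to 0.900 for the correlation. Lists called in the 4 list comparisons numbered 18 to 19, 17 to 20, 16 to 19 and 12 to 18.

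Under median centring genes moved by different amounts, the median of all genes in CoPS against CoNS became 0.31, and these values became positive: CSN2 0.22, CSN1S2 0.12, GLYCAM1 0.15, MUC15 0.53, ACSS2 0.17, SLC27A6 0.073, SLC39A8 0.40, CNN1 0.059, TPM2 0.13, COL1A1 0.22, BGN 0.38, COL1A2 0.25, CKM 0.083, FASN 0.014, SCD 0.050, LALBA 0.21, LTF 0.65, CSN3 0.30, CSN1S1 0.18 and TLR2 0.63. Of these only MUC15, SLC39A8, BGN, LTF and TLR2 lay above that median. Camera's direction changed for milk proteins 0.24, milk fat synthesis 0.39, lactose synthesis with transport and lactogenic signalling 0.40, myoepithelial and smooth muscle markers 0.47, fibroblast and extracellular matrix 0.42, cell cycle 0.20 and reference genes 0.76, of which reference genes alone were called, while the medians of milk proteins and cell cycle lay under that of all genes. The brightest TLR2 probe lay at 0.11 in CoPS against healthy, not called and under the median of all genes, 0.24, and the mean over its probes was 0.26 in CoPS and 0.049 in CoNS against healthy and 0.21 in CoPS against CoNS. IL6 in CoPS against CoNS was -0.014 with no background subtraction and -0.24 with the scanner's ratio. CSN3 in CoNS against healthy ranged from -0.17 to 0.14 as single replicates were left out, the ends being without CoNS replicate 3 and without CoNS replicate 4 of lactations 3 and 4.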

Other observations

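The values in this part were singled out after they had been seen. Group means (log2 ratio to healthy, n = 2 replicates, lactations 1 and 2 then 3 and 4) of the class I gene BOLA-N were 2.07 and 0.24 in CoPS and -0.11 and -3.92 in CoNS, and of JSP.1 1.75 and 1.35 in CoPS and -0.16 and -2.56 in CoNS. BOLA-N was below healthy in 4 of 4 CoNS replicates and above it in 4 of 4 CoPS replicates, while 2 of its 3 other probes were called higher in CoNS. The class II gene BOLA-DQA3 lay at 5.85 and -0.055 in CoPS and 0.0078 and -0.012 in CoNS, while BOLA-DQA2 lay at 1.85 and 2.33 in CoPS and 0.65 and 1.33 in CoNS. These genes are highly polymorphic in cattle, and each group held 2 pools.

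In CoNS, S100A12 lay at -0.0090 in lactations 1 and 2 and at 4.18 in lactations 3 and 4, and SAA2 at 1.98 and 4.75. NOS2 means were 0.49 and 0.90 in CoPS and 0.18 and 3.37 in CoNS.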
